A study of Caenorhabditis elegans with 2 samples.

How the data were processed

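Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed with an antibody against EFL-1 in whole hermaphrodite L1 larvae of the wild-type C. elegans strain N2. Per the labels, the larvae were grown at 26 °C and the libraries had a size range of 150 to 350 bp. The labels give 1 group with 2 biological replicates, taken from separate biosamples. No second condition belongs to the series, so no comparison between conditions was made.

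Lists of 3 kinds were used, each deposited on the builds ce10 and ce11. Per the text the authors deposited with the samples, a relaxed list of peaks and background was called for each replicate with a control, and a further relaxed list was called on the reads of both replicates pooled. A last set is described as thresholded by the irreproducible discovery rate (IDR), which measures how alike peaks rank in replicates. It was identical to the same number of top peaks of the pooled list on both builds, so its single peaks were those with the highest pooled scores. These are called the replicate lists, the pooled list and the IDR set. The aligner, the peak caller and their versions are not given in the sources used here. Each peak carries a peak score, deposited by the authors, whose scale is not stated, so scores were used only to rank or describe peaks within 1 list. Each peak also carries a −log10 q, deposited by the authors and read from the definition of the peak format; it stood at its ceiling of 4.04 in all 4835 peaks of the ce11 IDR set and was not used to rank them. Read numbers are not in the peak lists, so the depth of the libraries is unknown. The control library and the signal tracks were not analysed here, and how far a control removed signal at open or strongly transcribed sites could not be measured.

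All positions are on ce11, which is the assembly WBcel235 of the reference sequence used, with gene models of Ensembl release 115. The ce10 lists were used for counts only, with no conversion of coordinates. A protein-coding gene on the 6 nuclear chromosomes was called bound when a summit of the IDR set lay between 500 bp upstream and 200 bp downstream of its annotated start. That interval is called the promoter window, and where several summits fell in it the highest-scoring one gave the gene its values. In C. elegans many messages are trans-spliced and many genes lie in operons, so an annotated start can lie away from the site of transcription initiation. Genes starting within 500 bp downstream of the end of a gene on the same strand were marked as possible downstream operon genes.

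The top peaks of the replicates, as many as the IDR set holds, were matched within 100 bp of the summit and compared with 1000 random placements. Promoter and structural RNA shares were tested against 10000 random sets of positions on the same chromosomes. Divergent starts were tested against 10000 random sets of peaks spread evenly over promoter windows. A set of 16 gene lists with 666 entries was fixed before the data were examined; 659 entries matched a gene name, and 7 did not (nuf-2, smc-1, rad-54, hsp-16.11, hsp-16.49, opt-2 and bus-8). Each list was compared with all other protein-coding genes by a two-sided Fisher exact test, with Benjamini-Hochberg adjustment over the 16 lists and a threshold of 0.05. Where a cell of the table was 0, the odds ratio was computed with a correction for the empty cell. Genes are the units of these tests and are not replicates; p-values describe this peak set and not the spread between animals.

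The E2F consensus TTSSCGC, where S is C or G, and the cell cycle genes homology region (CHR) TTYGAA, where Y is C or T, were searched on both strands within 100 bp of each summit. Windows of the same width 500 bp to each side served as flanks, with an exact McNemar test against each side, of which the larger p is given. The motifs read backwards without complementing, CGCSSTT and AAGYTT, had the same base composition and served as a second control. Motif shares at the best peaks of gene lists were compared by Fisher exact tests, adjusted over 42 tests, a comparison added after the data were examined. Replicate agreement without the IDR selection, the spread of score ratios in parts of the IDR set and the test of ribosomal against replication genes were added then too. The difference in log10 score between peaks with and without the consensus was tested by 100000 permutations. Intervals are exact 95% intervals and cover counting error only.

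Genes were named by a rule fixed before the data were examined. It takes the genes of the 20 highest-scoring IDR peaks, every DREAM subunit, and for each other list the 3 bound members with the highest-scoring peaks and the first 2 unbound members in list order. It also takes the genes of the 5 promoter peaks whose rank differed most between replicates. Other genes named, among them the members given when a family is counted, were chosen after their values were seen.

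On simulated data, 200 of 200 planted gene starts were recovered. In 3 of 100 sets of uniform positions the promoter test gave a p under 0.05. Of 200 random gene lists, 0 passed the adjusted threshold beside 1 list with 20 of 40 genes planted, and 600 of 600 planted consensus sites were found. For planted replicate agreement of 70%, 70.1% was measured. Alternatives were a stricter peak set, each replicate alone, other windows, other backgrounds, other motif windows and other matching distances. With the nearest start within 2000 bp, each peak went only to the gene with the nearest start. Genes that share a peak could then not both be called bound by it. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.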

Results

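EFL-1 is the C. elegans counterpart of the mammalian E2F4 and E2F5 transcription factors and a subunit of the DREAM complex, which holds cell cycle genes in check in resting cells. Its binding was mapped by ChIP-seq in 2 biological replicates of whole L1 larvae grown at 26 °C. L1 is the first larval stage, in which most tissues are already formed. The IDR set held 4835 peaks on ce11 and 4865 on ce10. The relaxed lists held 28817 peaks for replicate 1, 30000 for replicate 2 and 30000 for the pooled reads. Read depth is unknown from these lists, and the scores given here are the authors' peak scores.

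The first comparison asked whether both replicates marked the same sites, and they did so most closely at the strongest ones. The peak 290 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit, ranked first in both replicates, with scores of 6341 and 9694. The peak at cdc-48.1, encoding an AAA ATPase that extracts proteins for degradation, ranked second in both. The peak upstream of rpl-35 ranked 3 in both. All 20 of the highest-scoring IDR peaks were among the top 100 of each replicate list. Of the 4835 top peaks of each replicate, 4029 (83.3%) lay within 100 bp of a top peak of the other, against 1.07% ± 0.147 (SD) in 1000 random placements, whose highest value was 1.55%. Of the IDR peaks, 98% had a summit within 100 bp in the list of replicate 1 and 99.5% in that of replicate 2, which follows in part from their selection. Without that selection, 94% of the top peaks of replicate 1 had a match anywhere in the list of replicate 2, and 95.4% the other way round.

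Across the 4718 IDR peaks matched in both lists, the scores gave Spearman's rho of 0.920 and Pearson's r of 0.946 on log10 scores. These values are across peaks, which are not independent replicates, and the IDR set was the top of the list called on the pooled reads of both. For the top peaks of either replicate matched in the whole list of the other, rho was 0.935. The log2 ratio of the scores of both replicates had an SD of 0.386 in the higher-scoring part of the IDR set and 0.663 in the lower-scoring part. Among promoter peaks, the 5 largest rank differences were at fbxb-72, pycr-4, oaz-1, ima-3, and the start shared by cids-2 and phip-1. The peak at pycr-4 scored 11.9 in replicate 1 and 125.3 in replicate 2, whereas that at fbxb-72 scored 88.8 and 40.5. All 5 of these peaks had scores between 95.3 and 140.4 in the IDR set, below its median of 179.8.

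**Figure D1:**
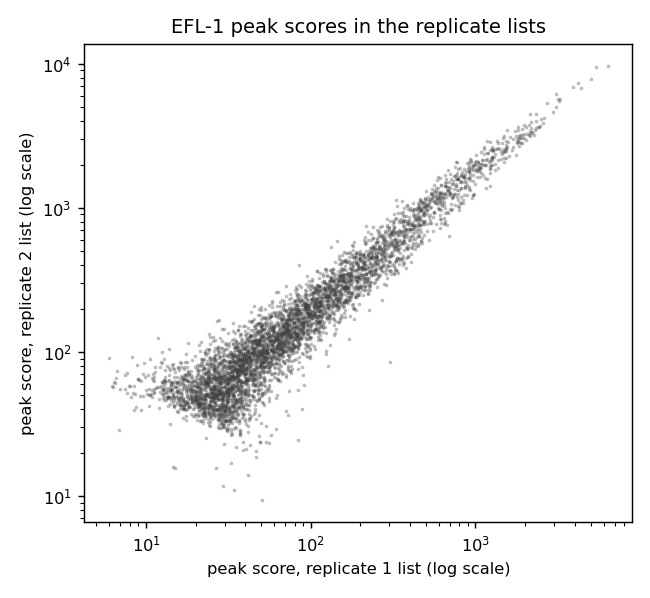
Peak score in the replicate 2 list (y axis, log scale) against the replicate 1 list (x axis, log scale), 1 point for each of the 4718 IDR peaks matched within 100 bp in both lists. The points lie closest to a line at high scores and spread at low scores, with an SD of the log2 score ratio of 0.386 and 0.663 in the higher- and lower-scoring parts.

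The strongest peaks lay at the starts of rpl-3, cdc-48.1 and rpl-35, and efl-1 itself was among the 20 highest. The peak at rpl-3 (III:3867288-3867825) had a score of 15978, that at cdc-48.1 (II:10563320-10563834) 14939 and that at rpl-35 (III:7854421-7854944) 12887. They were followed by citk-2 (11572), sec-61.G, a subunit of the protein translocation channel of the endoplasmic reticulum (11071), tasp-1 (10726), dld-1, the dihydrolipoyl dehydrogenase of mitochondrial enzyme complexes (9169), and eelo-2 (8918). One peak with a score of 8802 lay between the divergent genes rbd-1 and T23F6.3. The α-tubulin gene tba-2 (8705), F48A11.4 (8076) and Y39B6A.43 (7545) also ranked in the top 20. So did cox-5A, encoding a subunit of cytochrome c oxidase (6652), ddp-1 (6464), fbxl-2 (6316), W03F8.4 (6149), and the divergent pairs fipr-17 with Y48A6B.3 and Y53F4B.9 with Y53F4B.11. The peak ranked 15 (I:16780-17256) was the only 1 of these 20 outside all promoter windows, and 11 of the 20 held the E2F consensus.

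Most genes of the complex that EFL-1 belongs to had a peak at their start. The peak at efl-1 (V:16965596-16966099) ranked 12 of 4835 with a score of 8035; its summit lay 170 bp upstream of the gene start and it held the E2F consensus. Of the 8 DREAM subunit genes, 6 (75%, 95% interval 34.9 to 96.8) were bound, against 15.1% of other genes (odds ratio 16.8, Fisher exact adjusted p = 0.000585). They included lin-54, which encodes the CHR-binding subunit (score 3509) and shares its peak with the ribosomal protein gene rpl-12, lin-9 (3315), lin-53 (3155), lin-35, the gene of the retinoblastoma-like pocket protein (1777), and dpl-1, that of the dimerisation partner of EFL-1 (831). The genes lin-37 and lin-52 were not bound, with relaxed scores of 11.9 and 36.1 at their annotated starts. Both were marked as possible downstream operon genes, whose own starts need not be promoters. Among genes with any relaxed summit in their window, the enrichment of the DREAM list did not pass the test (odds ratio 3.49, exact adjusted p = 0.249).

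Summits concentrated just upstream of gene starts and were rare in coding sequence outside promoter windows. Of 4835 summits, 2401 (49.7%) lay in a promoter window, against 13.1% ± 0.486 (SD) of random positions. The permutation p was 0.0001, the smallest that 10000 random sets can give. The other kinds of sequence were counted only outside promoter windows. A position went to the first of 5′ UTR, coding exon, 3′ UTR, other exon and intron that held it. Counted so, 0.620% of all summits lay in coding exons, against 22% of random positions (permutation p = 0.0001). In introns lay 19.1%, against 32.8% (permutation p = 0.0001). The share in 3′ UTRs was 0.848% against 2.77% (permutation p = 0.0001), and that in 5′ UTRs 1.22% against 0.864% (p = 0.0094). The remaining 28.5% lay outside protein-coding genes and windows, a share that did not differ detectably from the 28.4% of random positions (permutation p = 0.90). Summits in promoter windows had a median position of -153 bp from the nearest start (quartiles -252 and -74), and 92.0% were upstream of it. The window itself reaches further upstream than downstream, and of all 4835 summits 72.6% were upstream of the nearest start.

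Pairs of divergently transcribed genes, such as rbd-1 with T23F6.3, and genes of structural RNAs were also marked often. Of the 2401 promoter peaks, 632 (26.3%) lay in the windows of genes on opposite strands. Of peaks placed at random in promoter windows, 11.4% did (permutation p = 0.0001). Random peaks were spread evenly over the windows, whereas 92.0% of promoter summits lay upstream of the nearest start. The test therefore cannot tell a preference for divergent pairs from this position. Within 200 bp of tRNA, rRNA, snRNA or snoRNA genes lay 351 summits (7.26%), against 0.514% of random positions (permutation p = 0.0001). Of 612 tRNA genes, 226 (36.9%) had a summit this close, as did 103 of 346 snoRNA genes and 31 of 129 snRNA genes, a breakdown made after the total was seen. None was found at the 20 rRNA genes, where random positions placed only 0.0187% of summits (permutation p = 0.637). Summits that were both near a structural RNA gene and outside all promoter windows made up 6.14% of all summits, against 0.451% of random positions.

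**Figure D2:**
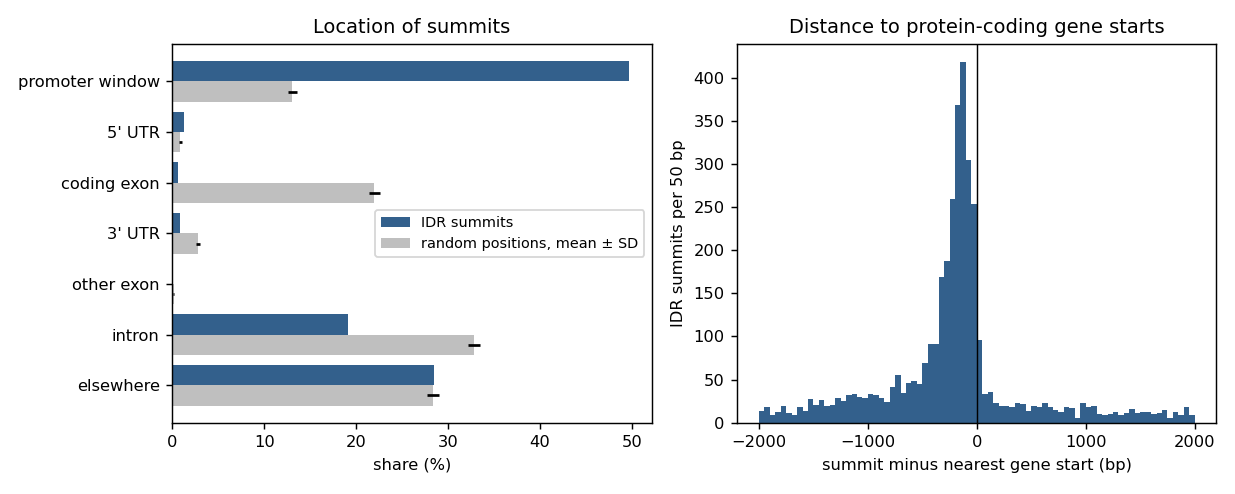
Left, share of IDR summits and of random positions (mean ± SD of 10000 sets) in promoter windows and, outside them, in each kind of annotated sequence (x axis, percent). Right, number of summits in bins of 50 bp (y axis) by distance from the nearest protein-coding gene start (x axis, bp, negative upstream). Promoter windows held 49.7% of summits against 13.1% of random positions, and the distances peak shortly upstream of the start.

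The X chromosome carried fewer bound genes than the autosomes. On X, 208 of 2731 protein-coding genes (7.62%) were bound, against 2819 of 17242 (16.3%) on the autosomes (odds ratio 0.422, 95% interval 0.362 to 0.489, Fisher exact p = 7.28e-37). Genes on X named by the fixed rule and not bound included the cyclin-dependent kinase gene cdk-4, with a relaxed score of 57.5, the heterochromatin protein gene hpl-1, the pharyngeal myosin gene myo-2, and the yolk protein genes vit-1 and vit-2. Peak density per megabase was highest on III (70.9) and I (67.2) and lowest on X (25). Among genes with any relaxed summit in the window the odds ratio was closer to 1, at 0.659 (Fisher exact p = 3.99e-06). With the higher-scoring part of the IDR set it was further from 1, at 0.266 (Fisher exact p = 2.09e-48).

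Genes of the DNA replication machinery were bound almost throughout. Of 45 replication genes, 37 (82.2%, 95% interval 67.9 to 92.0) had a summit at their start, against 15% of other genes (odds ratio 26.2, Fisher exact adjusted p = 1.29e-22). All 7 mcm genes, which encode the replicative helicase and a factor that activates it, were bound, as were 4 of 5 orc genes of the origin recognition complex, all 3 psf genes of the GINS complex and 3 of 4 rfc genes of the clamp loader. The highest scores were at pcn-1, encoding the sliding clamp PCNA (4069), orc-5 (3726) and the timeless homologue tim-1 (3531). The unbound members orc-2 and gmn-1, the geminin gene, had relaxed scores of 14.3 and 19.5. Of the 8 unbound replication genes, 6 were possible downstream operon genes, and without such genes 32 of 34 were bound (odds ratio 84.7, exact adjusted p = 6.78e-23). Against genes with any relaxed summit the odds ratio was 14.5 (exact adjusted p = 6.05e-09). With only peaks lacking TTSSCGC, a setting chosen after seeing the data, the list did not pass (odds ratio 2.07, exact adjusted p = 0.110). That follows from the 27 of 37 replication peaks that held the consensus, so it is no separate test of dependence on it.

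Most genes of mitosis and the kinetochore were bound as well. Of 53 genes, 43 (81.1%, 95% interval 68 to 90.6) were bound (odds ratio 24.4, exact adjusted p = 1.45e-25). The kinetochore genes kbp-4 (score 4180) and knl-3 (3140) and the condensin gene hcp-6 (2860) had the strongest peaks. The kinetochore gene kbp-2, with a relaxed score of 11.4, and the depolymerising kinesin gene klp-7, with no relaxed summit, were not bound. With the nearest start within 2000 bp, 34 of the 53 were bound (64.2%, odds ratio 8.69, exact adjusted p = 1.82e-13). DNA repair genes followed, with 24 of 44 bound (54.5%, odds ratio 6.76, exact adjusted p = 5.00e-09). Their strongest peaks were at the checkpoint clamp loader gene hpr-17 (5280), the translesion polymerase gene polh-1 (4650), which shares its peak with the ribosomal protein gene rps-22, and the nuclease gene fan-1 (3680), the last with its summit 114 bp inside the gene. The mismatch repair genes msh-6 and mlh-1 were not bound, and 15 of the 20 unbound repair genes were possible downstream operon genes. With the narrower window of 300 bp upstream to 100 bp downstream, 13 of the 44 repair genes were bound (29.5%, odds ratio 3.18, Fisher exact adjusted p = 0.00237). Without possible downstream operon genes in list and background, 20 of 25 were bound (80%, odds ratio 21.1, exact adjusted p = 1.12e-11).

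Cell cycle regulators did not pass the test as a list. Of 32, 9 were bound (28.1%, odds ratio 2.19, 95% interval 0.893 to 4.93, exact adjusted p = 0.0710). Strong peaks lay at the inhibitory kinase gene wee-1.3 (4529), at cyb-1, a cyclin B gene (3726), whose peak is the one between it and orc-5, and at cdk-1 (912). The cyclin E gene cye-1 had no relaxed summit, cdk-4 was unbound, and 0 of the 4 cdc-25 phosphatase genes were bound. With the top peaks of replicate 2 alone, 10 of the 32 were bound (odds ratio 2.53, exact adjusted p = 0.0326), and with those of replicate 1 alone also 10 (odds ratio 2.63, adjusted p = 0.0267), 1 gene more than with the IDR set.

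None of the 3 lists of germline, meiosis and oocyte genes passed the test, and strong peaks lay at particular germline and oocyte genes. Germ cells were not assayed apart from whole larvae, so binding confined to them may have been missed. For P granule and germline genes the count was 9 of 38 (23.7%, odds ratio 1.74, exact adjusted p = 0.226). All 4 mes genes were bound, among them mes-2 (5647) and mes-6 (1047), which encode subunits of the worm Polycomb complex; the other strong member was nos-3 (932). With the wider window of 1000 bp upstream to 500 bp downstream this list passed (odds ratio 2.2, Fisher exact adjusted p = 0.0312), as it did with the nearest start within 2000 bp (12 of 38, odds ratio 2.23, adjusted p = 0.0418). None of the 3 pgl and 4 glh genes, which encode core P granule proteins, was bound, and pgl-1 and pgl-2 had no relaxed summit. Meiosis genes had 4 of 32 bound (12.5%, odds ratio 0.799, exact adjusted p = 0.809), at him-17 (176), syp-3 (161), syp-2 (152) and syp-4. The genes syp-1 and htp-1 were unbound. Of the 32, 0 were bound in the higher-scoring part of the IDR set (odds ratio 0.133, exact adjusted p = 0.105). In the wider window 10 were (odds ratio 1.93, exact adjusted p = 0.136). Oocyte and early embryo genes had 4 of 36 bound (11%, odds ratio 0.699, exact adjusted p = 0.737). They included spn-4 (2105), gpr-2 (951) and gpr-1 (691), the last sharing its peak with the DNA repair gene polk-1, and not oma-1 or oma-2.

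Chromatin and small RNA genes passed the test with smaller odds ratios. Of 40 genes of chromatin regulation and the synMuv class, which antagonises vulval fate, 18 were bound (45%, odds ratio 4.6, exact adjusted p = 1.77e-05). The strongest peaks were at the H2A.Z gene htz-1 (2646), the remodeller gene isw-1 (2282) and the acetyltransferase gene mys-1 (1983), whereas lin-13 and hpl-1 were unbound. Small RNA pathway genes had 14 of 39 bound (35.9%, odds ratio 3.14, exact adjusted p = 0.00206), led by mut-15 (1297), rde-4 (1153) and mut-2 (779), and not rde-2 or rde-11. Small RNA genes did not pass in the higher-scoring part of the IDR set (odds ratio 2.24, exact adjusted p = 0.0924). Against genes with any relaxed summit, neither list passed, with an odds ratio of 2.33 (exact adjusted p = 0.102) for chromatin and 1.63 (adjusted p = 0.414) for small RNA genes.

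Ribosomal protein genes, chosen as a comparison group of strongly expressed genes, did not differ detectably from replication genes in the share bound (Fisher exact p = 0.797). Of 75, 64 (85.3%, 95% interval 75.3 to 92.4) were bound (odds ratio 33.3, exact adjusted p = 2.79e-40), 37 of 44 rpl genes and 27 of 31 rps genes. After rpl-3 and rpl-35, the highest score was at rps-12 (4896); rpl-16 and rpl-19 had no relaxed summit. With the narrower window only 49.3% were bound, fewer than the 75.6% of replication genes (Fisher exact p = 0.00692). With the nearest start within 2000 bp the shares were 56% and 80% (Fisher exact p = 0.00992). There each peak went only to the gene with the nearest start, so a gene with a peak in its promoter window could count as unbound. Heat shock and chaperone genes had 23 of 38 bound (60.5%, odds ratio 8.64, exact adjusted p = 7.95e-10), with the strongest peaks at the co-chaperone gene sti-1 (5050) and the chaperonin genes cct-1 (2747) and cct-8 (2646). Of the 8 cct genes 7 were bound, and 16 of 30 genes remained bound without them (odds ratio 6.43, Fisher exact p = 1.29e-06). The heat shock factor gene hsf-1 was unbound with a relaxed score of 25, and hsp-16.1 had no relaxed summit. Of the 4 hsp-16 genes counted, 2 were bound, hsp-16.2 and hsp-16.41. All 3 dnj genes of the list were bound, and 0 of 4 hsp-12 genes were. With the nearest start within 2000 bp, 13 of the 38 were bound (34.2%, odds ratio 2.51, exact adjusted p = 0.0213).

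Among differentiated tissues, cuticle and intestine genes were bound less often than other genes, and the neuron and muscle lists did not pass the test. None of 48 cuticle and hypodermis genes was bound (95% interval 0 to 7.40%, odds ratio 0.0575, Fisher exact adjusted p = 0.0016), rol-6 and rol-8 among them. With the nearest start within 2000 bp 2 of the 48 were bound (odds ratio 0.209, exact adjusted p = 0.0237). Of 42 intestine genes only erm-1, which encodes an apical membrane linker (365), was bound (2.38%, odds ratio 0.136, exact adjusted p = 0.0254), and vit-1 and vit-2 had no relaxed summit. In the higher-scoring part of the IDR set the intestine list did not pass (odds ratio 0.210, exact adjusted p = 0.164). Neuron genes had 6 of 49 bound (12%, odds ratio 0.781, exact adjusted p = 0.739), with ric-19 (3129), snb-1 (333) and egl-21 (152) highest and the cholinergic genes unc-17 and cha-1 unbound. Muscle genes had 9 of 40 bound (22.5%, odds ratio 1.63, exact adjusted p = 0.231), led by act-2 (728), unc-112 (306) and pat-6 (233), and not myo-1 or myo-2. With replicate 1 alone 12 muscle genes were bound (odds ratio 2.48, exact adjusted p = 0.0196). Over all alternatives run, the odds ratio ranged from 2.41 to 68.2 for DREAM, 2.07 to 84.7 for replication, 3.14 to 52.5 for mitosis, 3.18 to 21.1 for repair, 2.33 to 7.09 for chromatin and 1.63 to 4.47 for small RNA genes. The range was 3.33 to 54.4 for ribosomal protein, 2.51 to 12 for heat shock, 0.0848 to 0.782 for intestine and 0.0435 to 0.330 for cuticle genes. Larvae were assayed whole, so these counts do not tell in which cells a site was occupied.

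**Figure D3:**
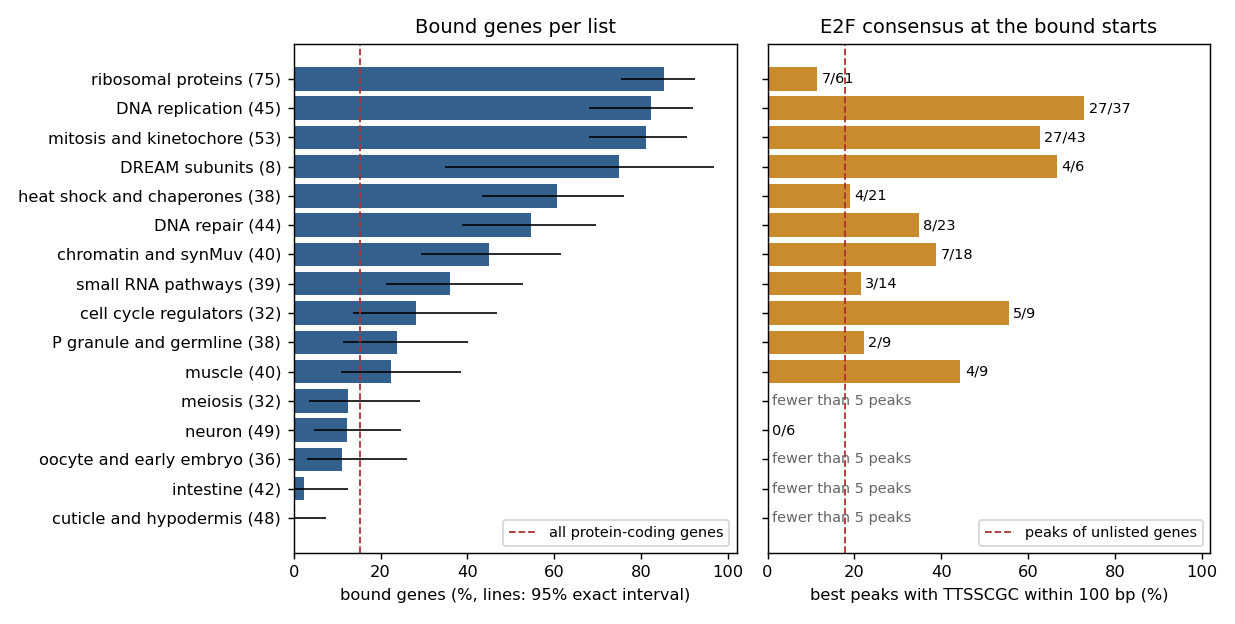
Left, percent of the genes of each list that were bound (x axis), with the number of genes in parentheses, exact 95% intervals as lines and the share of all 19973 protein-coding genes (15.2%) as a dashed line. Right, percent of the best peaks of each list with TTSSCGC within 100 bp of the summit (x axis), with counts, and the share at promoter peaks of unlisted genes (17.8%) as a dashed line. Ribosomal protein and replication genes were bound at 85.3% and 82.2%, while the consensus stood at 11.5% and 73.0% of their peaks.

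Peaks at replication and mitosis genes held the E2F consensus far more often than peaks elsewhere. TTSSCGC lay within 100 bp of the summit at 27 of 37 replication peaks (73.0%, pcn-1, orc-5 and tim-1 among them) and 27 of 43 mitosis peaks (62.8%, kbp-4 and knl-3 among them). At promoter peaks of genes on no list it lay at 378 of 2118 (17.8%). The Fisher exact adjusted p was 1.35e-11 for replication and 1.56e-09 for mitosis. At ribosomal protein peaks, rpl-3 and rpl-35 among those without it, the share was 7 of 61 (11.5%), lower than at replication and mitosis peaks together (53 of 79, 67.1%, exact adjusted p = 2.07e-10) and not detectably different from unlisted genes (adjusted p = 0.549). Shares at other lists did not pass the adjusted Fisher exact test, among them 4 of 6 DREAM peaks (adjusted p = 0.0740), 8 of 23 repair peaks (0.196), 7 of 18 chromatin peaks (0.127) and 4 of 21 heat shock peaks (1.00).

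Over the whole IDR set, 848 summits (17.5%) held TTSSCGC, against 6.80% of flanks (ratio 2.58, exact McNemar p = 6.80e-59). The reversed motif rose with it, to 10.5% of summits against 3.40% of flanks (ratio 3.08). Over the whole set the ratio of the consensus to its flanks was therefore not above that of its reversed control. In the higher-scoring part of the IDR set it was slightly above, at 3.24 against 3.13, and in all other settings run it was below. At replication and mitosis peaks the reversed motif did not differ detectably from unlisted peaks, at 13.9% against 11.9% (exact adjusted p = 0.95). At chromatin gene peaks it did, at 8 of 18 (44.4%, exact adjusted p = 0.00533). From the fifth of peaks with the highest scores to the lowest, the share with the consensus fell from 29% to 10.8%. The share with the reversed motif fell alike, from 17.6% to 6.31%, and that in promoter windows from 79.2% to 29.3%, so the trend was not particular to the consensus. Peaks with the consensus had a mean log10 score 0.231 higher than those without (permutation p = 1e-05, the smallest that 100000 permutations can give), with median scores of 308 and 165.

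The CHR sequence TTYGAA, to which LIN-54 binds, was rarer at summits than at flanks, at 44.8% against 53.5% (exact McNemar p = 9.65e-15). Its reversed form fell further, from 35.8% to 20.3%. In the higher-scoring part of the IDR set the CHR share was 52% at summits and 51% at flanks (exact McNemar p = 0.627), while the reversed form still fell from 33.8% at flanks to 21.3% at summits.

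**Figure D4:**
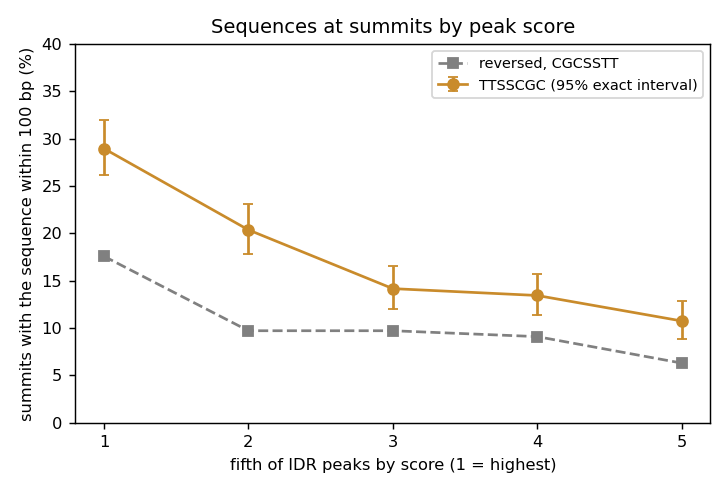
Percent of IDR summits with TTSSCGC (points with exact 95% intervals) and with the reversed motif CGCSSTT (squares) within 100 bp (y axis), in 5 equal groups of 967 peaks ordered by score (x axis, 1 is the highest). The consensus falls from 29% to 10.8% and the reversed motif from 17.6% to 6.31%.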

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

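Outside the IDR set, 5 peaks of the pooled list matched a top peak of both replicates, a signal in data that the main comparisons did not use. Their scores ran from 36.6 to 59.0, all under the lowest score of the IDR set (59.6). Of these 5, 3 lay in promoter windows, at the flippase gene tat-1, at the pair ash-2 and Y17G7B.20, and at the kinetochore gene czw-1, which an IDR peak with a score of 321.9 already marked as bound. The genes were named after their values were seen.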

How the results depend on the processing

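Of the alternatives given in this section, those restricted to peaks with or without TTSSCGC were chosen after seeing the data, and the others were planned. No paired analysis was possible because the series has 1 group. Taking the top peaks of the pooled list in place of the IDR set gave the identical set, so that alternative tested nothing. Promoter, structural RNA and divergent shares, the X odds ratio, bound genes and the E2F consensus kept their direction and side of the threshold under all alternatives run, with each replicate alone giving promoter shares of 48.3% and 50% and 2952 and 3049 bound genes. Lists bound more often numbered 8, but 9 without replicate 1, 10 without replicate 2, in the wider window and with the nearest start, 7 with and 6 without TTSSCGC, and 5 against genes with any relaxed summit, where DREAM, chromatin and small RNA genes lost the call beside other genes bound at 46.2%. Lists bound less often numbered 2, but 1 in the higher-scoring part of the set and 0 with peaks holding TTSSCGC, both with fewer bound genes. The CHR share, -8.68 points from its flanks, was 1.06 points above them in that higher-scoring part; the cause was not tested. Replicate matching of 83.3% became 76.2% at 50 bp, 85.4% at 200 bp and 91.6% for the top 1000 peaks; IDR peaks matched in the replicate 1 list at 91.4% and 99.6%, and in the replicate 2 list at 96.9% and 99.8%, for 50 and 200 bp. Of the single-list results, leaving out the identical set, 140 kept their call, 11 lost it and 9 gained it. Cell cycle regulators gained it in 6 settings, with an odds ratio of 3.30 in the wider window (exact adjusted p = 0.00197). With only peaks lacking TTSSCGC, replication (odds ratio 2.07, exact adjusted p = 0.110) and DREAM (2.41, 0.368) lost it, while mitosis did not (3.14, 0.00154). Genes whose only peaks held the consensus counted as unbound there, so these losses are no separate test of dependence on it. Read depth is unknown, so its effect was not measured.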

Other observations

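The families, the 8-base search, the rearrangements and, for AGACGCAG, its place and the tissue genes are tests chosen after the result was seen. Gene families grouped by the first letters of their names, 172 with at least 10 members, showed which other genes EFL-1 peaks favoured. Nuclear pore genes (npp) were bound at 20 of 26 (76.9%, odds ratio 18.8, Fisher exact adjusted p = 1.21e-10), and 11 of these 20 peaks held the E2F consensus. Genes of mitochondrial ribosomal proteins were bound at 17 of 28 for mrps (exact adjusted p = 9.67e-07) and 21 of 41 for mrpl (1.22e-06), proteasome regulatory genes (rpn) at 11 of 13 (1.06e-06), and Integrator (ints), RNA polymerase II (rpb) and cdk genes at 9 of 11 each (1.97e-05). In all, 23 families were bound more often and 31 less often than other genes.

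Among the families bound less often were those of several chemoreceptors. None of 193 str, 109 srw and 101 srx chemoreceptor genes was bound (exact adjusted p = 1.34e-12, 5.76e-07 and 1.34e-06). C-type lectin genes (clec) had 4 of 240 bound (exact adjusted p = 5.92e-11), collagen genes (col) 5 of 156 (1.97e-05), neuropeptide-like genes (nlp) 1 of 71 (0.00124) and major sperm protein genes (msp) 0 of 31 (0.0336).

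Ribosomal protein genes were bound more often than other genes. Their share of bound genes was not below that of replication genes with the main window (85.3% and 82.2%). It was below with the narrower window (49.3% and 75.6%) and the nearest start (56% and 80%), where genes sharing a peak could not both be bound by it. The consensus stood at 11.5% of their peaks, below the 67.1% at replication and mitosis peaks and not detectably different from the 17.8% at promoter peaks of unlisted genes (Fisher exact adjusted p = 0.549), the values that signal at active promoters without an E2F site would need. Signal at strongly transcribed loci of any kind would need peaks at structural RNA genes as well. There lay 7.26% of summits, against 0.514% of random positions. However, 0 of 20 rRNA genes had a summit within 200 bp, where random positions placed only 0.0187% of summits. How reads that match several places were treated is not known, so this absence has little weight. Collagen genes (5 of 156) and cuticle genes (0 of 48) were rarely bound, but transcription was not measured here. Both explanations stay open. EFL-1 may also reach these genes by another route; the series holds 1 group, so no biological explanation of this pattern was tested.

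The consensus was commoner at summits than 500 bp away, but of the 180 orders of its letters that keep a CG pair, 35 (19.4%), itself included, had a ratio at least as high, so base and CpG composition may account for the excess over all summits. Without the peaks that hold AGACGCAG the share was 8.89%, which does not remove this reading. For replication and mitosis peaks the measure was the share at summits, not the ratio to flanks. By share over all summits, other orders stood above the consensus (17.5%), such as CTSCGTS at 26.3%. On the other strand AGACGCAG, found at 17.9% of summits, holds a match to CTSCGTS, so that share does not measure composition alone. At the replication and mitosis peaks the values argue against composition alone, since only the consensus itself reached its own share (0.556% of orders). It stood at 67.1% of the 79 peaks, against 51.9% for the next highest order and a median of 6.33%. A candidate explanation for that part is direct E2F binding, a hypothesis found and tested on the same peaks.

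The most enriched 8-base sequence was AGACGCAG, within 100 bp of 864 summits (17.9%) against 1.24% of flanks (exact McNemar p = 6.25e-190). The tables argue against a sequence of annotated promoters alone, since it was commoner outside promoter windows (21.1%) than inside them (14.6%, Fisher exact p = 4.46e-09) and commonest, among the places compared, over 1000 bp from any annotated gene start (25.8%, p = 7.22e-15 against promoter windows). An element that acts apart from E2F is a candidate explanation: at promoter peaks it occurred with TTSSCGC less often than by chance (odds ratio 0.704, Fisher exact p = 0.0246), as it did outside the windows (0.728, p = 0.0324), so this was not particular to promoters, while its lower share at replication and mitosis peaks, 5 of 79 against 324 of 2118, fails correction over 42 tests (p = 0.0244, adjusted p = 0.126). Accessible promoters that many antibodies pull down cannot be told apart from such an element at promoters. Pooled peaks outside the IDR set held the sequence at 3.11% against 1.08% of flanks (exact McNemar p = 5.75e-57), which accessible promoters would need. However, only 13 tissue genes had the sequence in their window, of which 6 were bound (odds ratio against other genes with it 1.35, 95% interval 0.371 to 4.71). Unannotated promoters, enhancers and peaks of other antibodies were not analysed here.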
